A study of Mus musculus with 6 samples.

How the data were processed

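Chromatin from EML cells, a mouse line of blood precursors, was studied in a lin-CD34+ and a lin-CD34- population separated by magnetic beads and by flow sorting, per the labels' protocols. Cells were fixed in 1% formaldehyde for 10 min and the reaction was stopped with 0.125 M glycine. The labels list 6 libraries: ChIP-seq of STAT3 and of SOX4 in lin-CD34+ cells, ChIP-seq of GABPa in lin-CD34- cells, a control library in each population, and ATAC-seq in lin-CD34+ cells. The 2 control libraries are titled as input while the labels give normal IgG as their antibody, and no peak list of theirs was used here. ATAC-seq used 50000 cells by one passage of the protocol text, and another passage gives a higher number. Every group had 1 library, so there were no replicates, and no p-value or SD across peaks or genes was computed.

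The submitters' processing notes name CASAVA 1.7, Bowtie2, HOMER, SAMtools, Picard and MACS2 and the mouse build mm10, without the role or order of each. The column names of the ChIP lists are those of an older MACS table, and the settings of the peak caller are not given in the sources used here. The deposited tag counts are whole reads counted in each peak, per the file headers. The deposited score is −10 times the log10 of the peak caller's p-value, per the file headers. The fold enrichment is the peak caller's ratio over its background, as the authors deposited it. The authors' false discovery rate is given in percent. Scores and folds belong to each peak and were used only to rank or describe peaks within a list. The values showed a fold of at least 10, a false discovery rate under 5% and no peak more than 5000 bp upstream of its nearest transcription start site (TSS), so peaks farther upstream were not analysed here. The ATAC list holds positions and annotation without a score, and whether reads were shifted for the transposase is not given in the sources used here.

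The SOX4 list had 3016 peaks, the STAT3 list 885 and the GABPa list 2525. The ATAC list had 195295 entries at 143365 distinct positions, and 51930 entries repeated the interval of another. Distinct intervals were used in overlaps, and all entries in the promoter share as first stated. Library totals are not given in the sources used here, so depth was seen only as tags per peak, with medians of 10 for SOX4, 14 for GABPa and 30 for STAT3. Positions are 1-based on mm10. No genome sequence was used here, so the planned comparison of motifs in peaks and flanks, with all its alternatives, was not run.

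A promoter peak lay within 1000 bp of a TSS by the authors' distance column. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Overlap needed at least 1 bp. Each overlap was set against 1000 random placements of the same peak widths on the same chromosomes, and against 1000 placements at the same distance from the TSS of a random gene. Placements in gene bodies and their upstream 5000 bp were added after seeing the data, because the lists hold few other positions. The gene table used for placements (GRCm38.p6, the assembly named mm10) has no strand. Strand was settled from the peaks' distances for 18687 of its 26220 genes with a curated transcript and drawn at random for the other 7533. A first version of these placements used only TSSs settled by at least 2 listed peaks, which favours open genes. It was replaced after its results had been seen, and its values are given with the alternatives. Of the 20691 gene symbols in the lists, 19841 were found in the gene table.

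Genes with promoter peaks of a pair of factors were compared with the product of the gene numbers divided by 20691. The 21 gene lists were fixed before the data were examined, as were the tests, the alternatives not described as added and the rule for named genes. Each list's members with a promoter peak were compared with 10000 random gene lists of the same size, and for the factors also with random lists matched on an ATAC promoter peak. Only genes named in at least 1 of the 4 peak lists counted as members or were drawn, so genes with no peak anywhere are missing from every total, for example 5 of 18 erythroid markers. A list was called above or below the random range past the percentile 97.5 or 2.5. The named genes were the nearest genes of the 10 highest scores per factor, up to 4 members per gene list with the highest-scoring promoter peak, the genes Stat3, Sox4, Gabpa, Tcf7 and Runx1 with every peak, and genes with promoter peaks of all 3 factors. Some genes that met this rule or were shared between lists are not reported here. Alternatives covered the overlap rule, the promoter window, the score, repeats, chromosomes, merged entries, fixed widths and backgrounds.

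Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The steps were tested on simulated data. Overlaps matched a plain search for 500 of 500 intervals. With 10% of SOX4 peaks planted in open chromatin, 11.8% of the 3016 peaks overlapped against 12.0% to be recovered. Simulated STAT3 lists gave 51.5% against 51.5% with 50% planted, and GABPa lists 15.5% against 15.4% with 10% planted. Of 20 SOX4 lists drawn by distance-matched placement, 19 fell in the middle range. For STAT3 promoters, 3 of 200 random lists of 40 genes were called, and 200 of 200 with 5 planted members. The rank implied by a rounded false discovery rate was at or below the true rank in 971 of 1000 simulated values and exact in 418.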

Results

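Binding of 3 transcription factors and chromatin accessibility were mapped in EML cells, a mouse line of blood precursors that can be sorted into a lin-CD34+ and a lin-CD34- population. STAT3, a cytokine-activated factor, and SOX4, an HMG-box factor, were mapped in lin-CD34+ cells. GABPa, an ETS-family factor, was mapped in lin-CD34- cells, and open chromatin by ATAC-seq in lin-CD34+ cells. Each group was 1 library without a replicate, so differences between factors could not be set against a spread between libraries, and GABPa differed from the rest in population as well as antibody. Median tags per listed peak were 30 for STAT3 (range 11 to 112), 10 for SOX4 (8 to 29) and 14 for GABPa (10 to 215). Median peak widths were 311 bp for STAT3, 167 bp for SOX4, 1021 bp for GABPa and 132 bp for distinct ATAC intervals. Intervals in brackets after a share are exact 95% intervals, which cover counting error only.

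The first comparison asked where in the genome each factor bound. STAT3 peaks lay near gene starts: 416 of 885 (47.0%, 43.7 to 50.4) were within 1000 bp of a TSS, 11.3 times the share of random placements in gene bodies and their upstream 5000 bp. SOX4 peaks were mostly intronic, 2444 of 3016 (81.0%, 79.6 to 82.4), and 160 (5.31%, 4.53 to 6.17) were in promoters, 1.28 times the placements' share. GABPa peaks in lin-CD34- cells were intermediate, with 354 of 2525 in promoters (14.0%, 12.7 to 15.4), 3.38 times the placements' share, and 1885 in introns. The TSS sets were unlike: the authors' distances for peaks, and 1 gene end per gene for placements, random for 7533 of 26220 genes. These ratios are therefore rough, and 1.28 for SOX4 cannot be read as an excess. ATAC entries lay in promoters in 25.9% of cases, and in 14.1% (13.9 to 14.2) when each distinct interval counted once. Introns also held 74.7% of GABPa peaks and 75.4% of ATAC intervals. All lists hold intergenic peaks only within 5000 bp upstream of a TSS. The intronic shares depend on that limit, and no placement share for introns was computed.

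**Figure D1:**
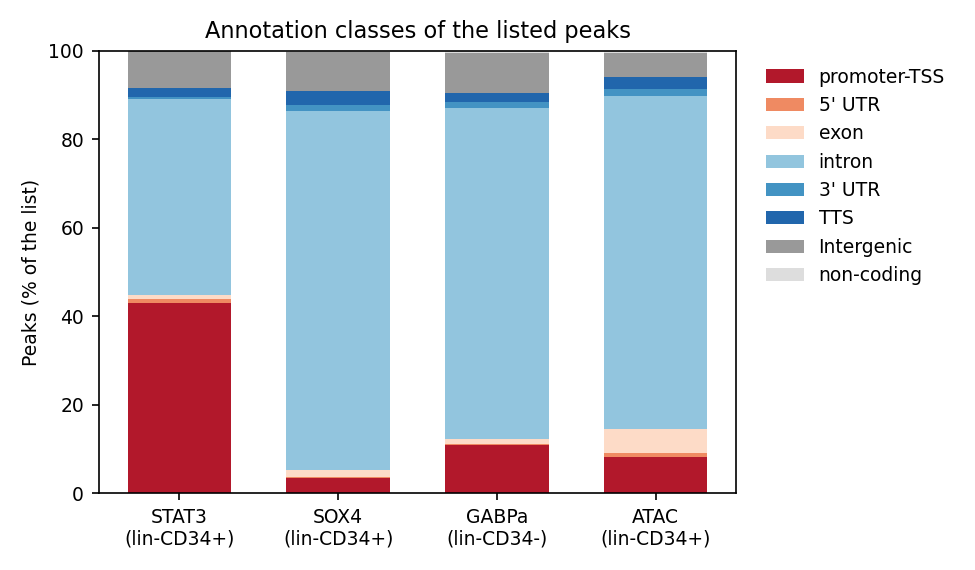
Stacked bars give the percentage of each list's distinct peaks (y axis) in each annotation class of the authors' table, for STAT3, SOX4 and ATAC in lin-CD34+ cells and GABPa in lin-CD34- cells. The promoter-TSS class held 43.1% of STAT3 peaks, 3.45% of SOX4 peaks, 10.9% of GABPa peaks and 8.11% of ATAC intervals.

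The strongest STAT3 peaks were at Copg1, a coatomer subunit, and Nfat5, a factor of the osmotic stress response. The Copg1 peak (chromosome 6, 87887646 to 87888024, mm10) lay at −105 bp from the TSS with 51 tags, a score of 216 and a fold of 37.1. The Nfat5 peak (chromosome 8, 107293208 to 107293558) lay at −87 bp with 57 tags and a fold of 35.4. Naa25, an N-terminal acetyltransferase subunit, Nat10, an RNA acetyltransferase, and Txnl4b also had promoter peaks among the 10 highest scores, with 89, 49 and 81 tags. The other strong STAT3 peaks were in introns of Commd10, Apol9b, Dnah6 and Nceh1, a cholesterol ester hydrolase, and near the deacylase gene Sirt7. The Dnah6 peak was in an ORR1D1 element, and Apol9b belongs to a family of similar copies, so these assignments are uncertain. In all, 5 of these 10 peaks were in promoters and 9 overlapped an ATAC peak, the exception being Commd10.

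The strongest SOX4 peaks were all intronic and none of the 10 overlapped an ATAC peak. Their nearest genes included Tmem186, the sodium channel gene Scn8a, Wars2, the potassium channel subunit gene Kcns2, the mineralocorticoid receptor gene Nr3c2, Akap6, Nmnat2, Smtn and Zfp710. The Tmem186 peak (chromosome 16, 8593792 to 8593963) lay 43824 bp from that gene's TSS with 14 tags and a fold of 21.8. The Nr3c2 peak (chromosome 8, 76906443 to 76906589, intron 1 of 8) had 13 tags and a fold of 26.4. Of 9 SOX4 peaks tied at the lowest score among these 10, the 4 with the highest fold (Akap6, Nmnat2, Smtn and Zfp710) were named. These 10 peaks rested on 13 to 21 tags, and that at Nmnat2 lay in an annotated repeat.

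Of the 10 strongest GABPa peaks 8 were in promoters, and all 10 overlapped a lin-CD34+ ATAC peak. The Cltc peak, at the clathrin heavy chain gene (chromosome 11, 86757517 to 86758278), lay at −405 bp from the TSS with 107 tags, a score of 1738 and a fold of 57.4. Eif3k, a translation initiation factor subunit, had 179 tags and a fold of 57.5, and Papd4, a poly(A) polymerase, 203 tags and a fold of 59.6. Mrpl30, a mitochondrial ribosomal protein gene, Vti1a, Rmnd1, Tprgl and Orc2, a subunit of the origin recognition complex, also had promoter peaks, with 194, 176, 91, 174 and 105 tags. Sec24c, of the vesicle coat, and the proteasome gene Psmc1 were nearest to peaks whose centres lay at −1401 bp and −2373 bp from their TSSs. The Sec24c peak was 3202 bp wide and annotated to a B1_Mus1 repeat. It covered the STAT3 promoter peak at −49 bp of Sec24c, so it reached that promoter.

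The second comparison asked whether bound sites were open in lin-CD34+ cells. STAT3 peaks overlapped ATAC peaks in 694 of 885 cases (78.4%, 75.6 to 81.1), 25.1 times the share of random placements and 3.88 times that of placements at matched TSS distance. SOX4 peaks overlapped in 163 of 3016 cases (5.40%, 4.62 to 6.27), 2.39 times the random placements but 0.990 times the matched ones, at their percentile 46.1. GABPa peaks of lin-CD34- cells overlapped lin-CD34+ ATAC peaks in 425 of 2525 cases (16.8%, 15.4 to 18.3), 2.84 times the random and 0.904 times the matched placements. The random placements covered 2724 Mb, whereas the lists are mostly confined to gene bodies and their upstream 5000 bp, 1172 Mb. That limit alone raises ratios to random placements, so 2.39 for SOX4 does not by itself show a preference for open chromatin. Against placements in gene bodies and their upstream 5000 bp, added after seeing the data, the ratios were 12.6 for STAT3, 1.18 (1.01 to 1.37) for SOX4 and 1.21 (1.10 to 1.32) for GABPa. The GABPa result thus changed direction with the choice of placement, and the SOX4 result was inside the matched range and above the others. With the placements first used, on genes with at least 2 listed peaks, SOX4 was below the matched range (0.805, percentile 0.1), and the gene-body ratios of 1.05 for SOX4 and 1.08 for GABPa were inside the range. The shares also depended on the overlap rule: with at least 50% of the peak covered they were 2.32% for SOX4 and 5.03% for GABPa, by peak centre 2.65% and 6.69%, and for STAT3 73.7% with the first of these rules. With fixed 200 bp widths the GABPa share was 9.90%.

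**Figure D2:**
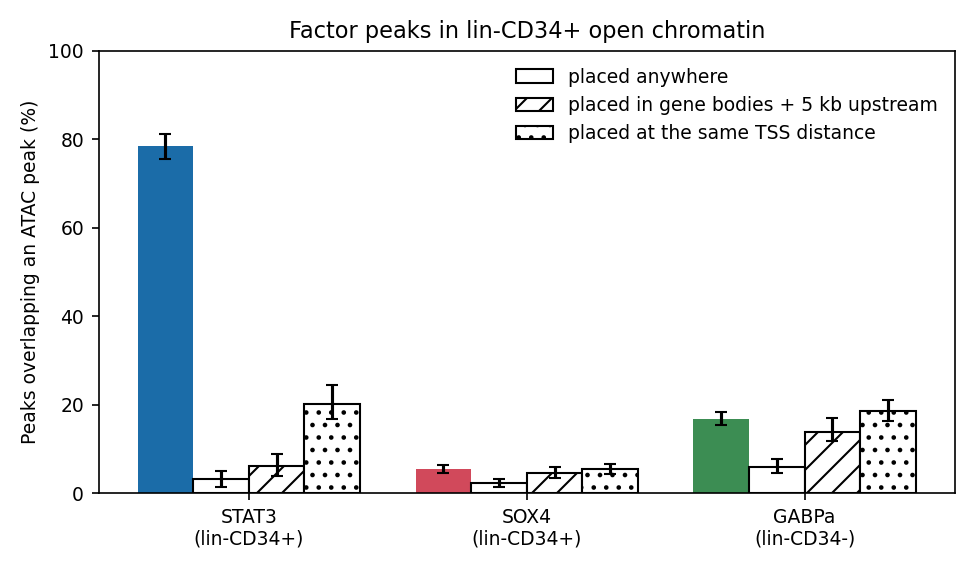
Bars give the percentage of each factor's peaks overlapping an ATAC peak (y axis), coloured for the observed share with its exact 95% interval and white for the mean of 1000 placements of 3 kinds with their lowest and highest values. The STAT3 bar at 78.4% stands above all its placements, while the SOX4 bar at 5.40% and the GABPa bar at 16.8% stand near the distance-matched means of 5.46% and 18.6%.

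Promoters accounted for much of the overlap of GABPa and part of that of SOX4. Of STAT3 promoter peaks 96.4% (94.1 to 98.0) were open, and of its other peaks 62.5% (57.9 to 66.9), 9.65 times the matched placements. GABPa promoter peaks were open in 68.9% (63.8 to 73.7), 1.53 times the matched placements, and its other peaks in 8.34%, 0.582 times. SOX4 promoter peaks were open in 23.8% (17.4 to 31.1) against 21.9% of matched placements, and its other peaks in 4.38% (3.66 to 5.19) against 4.54%. With peaks in annotated repeats left out, an alternative chosen after seeing the data, 27.1% of GABPa peaks were open, 1.20 times the matched placements, and 6.68% of SOX4 peaks, 1.14 times. Among peaks above the median score the matched ratios were 1.18 for GABPa and 1.08 for SOX4. GABPa thus went from below its matched placements (percentile 0.9) to above all of them (percentile 100) in both subsets, while SOX4 stayed inside its matched range (percentiles 46.1, 94.6 and 77.9). The placements of repeat-free peaks could still fall in repeats, where 21.0% of ATAC intervals lay. Observed and placed peaks were therefore unlike there, and no conclusion is drawn from the repeat-free ratios.

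Higher-scoring peaks were more often open for STAT3 and GABPa. From the lowest to the highest of 5 score classes the open share went from 54.2% (46.6 to 61.7) to 98.3% (95.1 to 99.6) for STAT3 and from 8.91% (6.57 to 11.7) to 41.2% (36.9 to 45.6) for GABPa. For SOX4 it rose in each class, from 4.47% (2.97 to 6.44) over 5.14%, 5.31% and 5.80% to 6.30% (4.50 to 8.55), with intervals that overlap. The median score inside and outside open chromatin was 99.7 and 79.5 for STAT3, 148 and 94.7 for GABPa, and 65.4 and 64.9 for SOX4. The median fold enrichment differed by 0.27 for STAT3, 1.55 for GABPa and 0 for SOX4. From the lowest to the highest score class the promoter share also went from 32.2% to 54.2% for STAT3 and from 3.56% to 39.4% for GABPa. For SOX4 it was 5.46% and 5.31%. The LINE-1 share of GABPa peaks fell from 41.8% to 9.90%. Score was therefore not separated from promoter position or repeats.

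**Figure D3:**
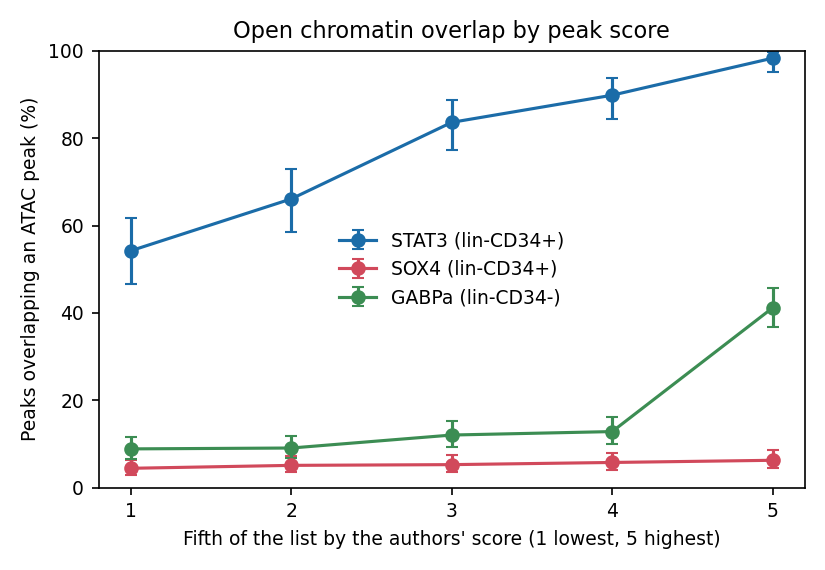
Points give the percentage of peaks overlapping a lin-CD34+ ATAC peak (y axis) in 5 classes of the authors' score (x axis, lowest to highest) for each factor, with exact 95% intervals. STAT3 rose from 54.2% to 98.3% and GABPa from 8.91% to 41.2%, with the GABPa step between the last classes, while SOX4 rose from 4.47% to 6.30%.

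The third comparison asked whether the factors shared sites. STAT3 and GABPa, mapped in different populations, met at promoters: 71 STAT3 peaks overlapped a GABPa peak against a mean of 6.03 matched placements, 59 of the 71 in promoters and 95.8% (88.1 to 99.1) in open chromatin. SOX4 overlapped STAT3 at 58 peaks against 1.53 matched placements, with 7 in promoters. The STAT3 peaks at those sites were open in 15.5% (7.35 to 27.4) against 82.8% (80.1 to 85.3) of its other peaks. The labels list 1 control library for lin-CD34+ cells, and which control the peak caller used for SOX4 and STAT3 is not given in the sources used here. SOX4 and GABPa overlapped at 51 peaks against 8.93 matched placements, and 11.8% (4.44 to 23.9) of these SOX4 peaks were open. At full widths the random placements gave 3.54 for SOX4 with GABPa and 1.135 for STAT3 with GABPa. With 200 bp around each centre SOX4 and GABPa overlapped at 14 peaks against 1.13 random placements, and STAT3 and GABPa at 24 against 0.302. With repeats left out SOX4 and GABPa overlapped at 28 against 1.15. Among SOX4 peaks above the median score the overlaps with STAT3 and GABPa peaks of the same kind were 7 and 18, against 0.156 and 0.735. A peak of all 3 factors lay at Zbtb7a, a zinc finger repressor gene, 1150 bp from the TSS (STAT3 peak on chromosome 10, 81137232 to 81137611, 51 tags).

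Promoter peaks of both STAT3 and GABPa were found at 52 genes, 8.23 times the 6.32 of independent lists. They included Mrpl30, Eif3k, Eif4e, the splicing factor genes Prpf18 and Prpf19, the tRNA synthetase gene Yars and the replication licensing gene Cdc6. SOX4 and STAT3 shared 11 promoter genes against 3.13, among them Srsf1, Rcc2, Tgif1 and Malat1. SOX4 and GABPa shared 12 against 2.44, among them Psmd7 and Acp2. No gene had promoter peaks of all 3 factors, and within 5000 bp there were 6: Ncoa4, Rcc2, Rfx3, Sec24c, Slc25a38 and Zbtb7a. Genes of these pairs named here outside the fixed rule were chosen after their values were seen.

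The fourth comparison asked which gene groups had bound or open promoters. STAT3 bound the promoters of 9 of 63 splicing factor genes (14.3%) against 1.25 in random lists, including Hnrnpl with 39 tags, Srsf1 with 58, Hnrnph1 with 38 and Prpf19 with 53. Among blood stem and progenitor transcription factors STAT3 had promoter peaks at 4 of 27 (14.8%): Runx1, its partner subunit gene Cbfb, Nfe2 and the GATA cofactor gene Zfpm1, with 40, 48, 36 and 23 tags. It was also above the random range at mitochondrial biogenesis genes (3 of 24: Lonp1, Tomm20, Hspe1), proteasome subunits (4 of 46: Psmb2, Psma6, Psma2, Psma3), translation initiation factors (4 of 50: Eif3d, Eif4e, Eif3k, Eif4b) and erythroid markers (2 of 13: the transferrin receptor gene Tfrc and Hemgn). Within 5000 bp of a TSS initiation factors and erythroid markers fell inside the range, and by nearest gene at any distance these and the proteasome did (percentiles 89.6, 94.4 and 91.8). Erythroid markers had no promoter peak above the median score. The lists above the range with those higher scores still numbered 6, so another list had joined. In the JAK-STAT and known target list only Ptpn11, a phosphatase gene, had a STAT3 promoter peak among 36 genes, and in the receptor list only Kit among 22. The STAT3 list may lack about 101 peaks stronger than any listed, by its false discovery rates (implied rank 102), so a missing peak does not show an unbound gene. Lists inside the random range were cytosolic ribosomal proteins (4 of 79), mitochondrial ribosomal proteins (4 of 72), oxidative phosphorylation (3 of 78), tRNA synthetases (2 of 35), cell cycle (2 of 34, Cdk4 and Cdc6), chromatin regulators (2 of 33, Kdm5a and Bap1) and the Wnt pathway (1 of 33, Dvl2). Olfactory receptors were below the random range, with 0 of 381. No promoter peak was found among 32 Hox genes or the neutrophil and monocyte, lymphoid, mast cell and megakaryocyte, and non-blood markers. These lists were inside the random range. STAT3 promoter peaks lay at 410 of 20691 genes, so a short list without one does not show avoidance.

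GABPa in lin-CD34- cells had 6 lists above the random range at promoters. Above the random range were mitochondrial ribosomal proteins (5 of 72, led by Mrpl30 with 194 tags and Mrpl33 with 51), mitochondrial biogenesis (3 of 24: Ssbp1, Gabpa, Tomm22), cytosolic ribosomal proteins (5 of 79, led by Rpl41 with 140 tags and Rpl32 with 51), cell cycle and replication (3 of 34: Mcm3, E2f2, Cdc6), proteasome subunits (3 of 46: Psmd7, Psme2, Psmc2) and translation initiation factors (3 of 50: Eif3k, Eif4e, Eif1a). Initiation factors fell inside the range, at percentile 97.0, against random lists matched on open promoters in lin-CD34+ cells. Within 5000 bp of a TSS mitochondrial ribosomal proteins (percentile 91.9) and mitochondrial biogenesis fell inside, above the median score proteasome subunits did (93.4), and by nearest gene only proteasome subunits stayed above. Splicing factors (3 of 63), tRNA synthetases (2 of 35, Yars and Rars) and oxidative phosphorylation (2 of 78) were inside it, although the Atp5a1 promoter peak, at an ATP synthase subunit gene, had 212 tags and a fold of 61.1. Slamf1 was the only receptor gene with a GABPa promoter peak and Mcl1 the only gene of the JAK-STAT list. Blood stem and progenitor factors (27 genes), the Wnt pathway, chromatin regulators, Hox genes and all 5 marker lists had none, yet none of them was below the random range. GABPa promoter peaks lay at 319 of 20691 genes, so a short list without one does not show that GABPa avoided it. Of 381 olfactory receptors Olfr1033 and Olfr1208 had a peak, the former in an MMVL30 element and both uncertain for a large gene family.

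No gene list was above or below the random range for SOX4 promoter peaks. Those peaks lay at 158 of 20691 genes, so a short list without one does not show avoidance. By nearest gene at any distance chromatin regulators were above the random range (11 of 33 against 4.15) and olfactory receptors below, the latter also within 5000 bp (percentile 2.06). Random lists were not matched on gene length, and most SOX4 peaks were intronic. The calls by nearest gene may therefore reflect gene length, which was not tested. The SOX4 promoter peaks in the gene lists were at single genes: Rpl22, Mrps15, Psmd7, Srsf1 and the polycomb gene Rnf2, on 18, 10, 12, 10 and 11 tags. Only that at Srsf1 overlapped an ATAC peak.

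**Figure D4:**
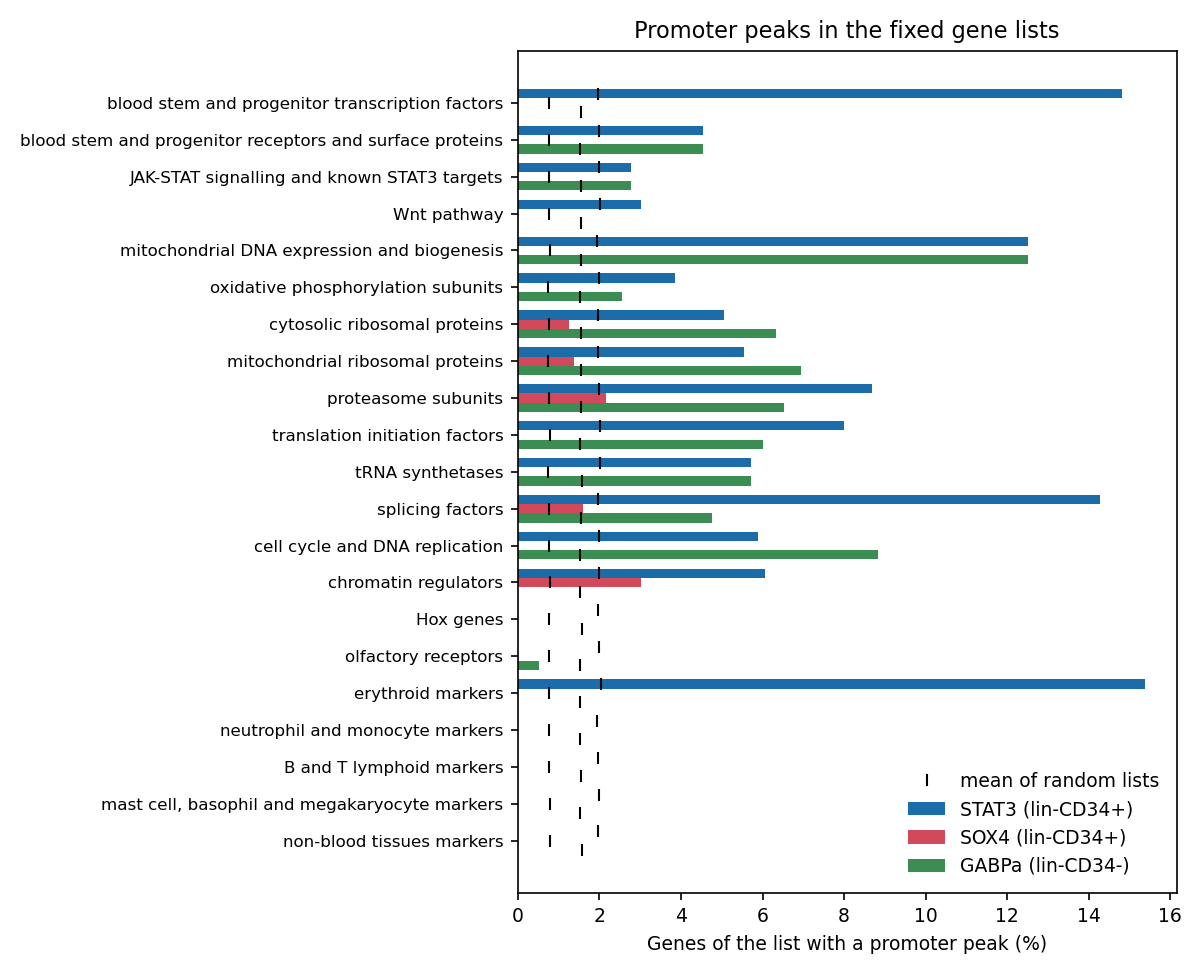
Bars give the percentage of genes in each of 21 fixed lists (y axis) that had a promoter peak of each factor (x axis), and black ticks the mean of 10000 random lists. STAT3 reached 14.8% of blood stem and progenitor transcription factors and 14.3% of splicing factors, and GABPa 6.94% of mitochondrial ribosomal protein genes.

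Open promoters in lin-CD34+ cells covered most blood stem cell regulators, and fewer lymphoid and non-blood marker genes than random lists. ATAC promoter peaks were found at 14107 of 20691 genes, at 25 of 27 blood stem and progenitor factors (all but Ikzf2 and Prdm16) and at 35 of 36 genes of the JAK-STAT list. Genes without a peak in any of the 4 lists are left out of these totals. The X chromosome held 0.610% of ATAC intervals against 4.38% of gene bodies with their upstream 5000 bp. A missing ATAC peak at an X-linked gene therefore does not show a closed promoter. Lists above the random range were also the Wnt pathway (30 of 33), chromatin regulators (29 of 33), cell cycle (32 of 34) and the 7 lists of oxidative phosphorylation, ribosomal proteins of both kinds, proteasome, initiation factors, tRNA synthetases and splicing factors. Below it were olfactory receptors (166 of 381), B and T lymphoid markers (7 of 18, without Pax5, Ebf1, Rag1 or Cd3e) and non-blood markers (11 of 23, without Alb, Afp or Neurod1). Inside it were receptors (18 of 22), mitochondrial biogenesis (20 of 24), Hox genes (19 of 32), erythroid (7 of 13, without Gata1 and Klf1, and with 5 of the 18 chosen genes in no list), neutrophil and monocyte (11 of 18) and mast cell and megakaryocyte markers (13 of 16). With a promoter window of 5000 bp 2 lists in place of 12 were above the range and none below.

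At the genes of the factors themselves, GABPa bound its own promoter. The Gabpa peak (chromosome 16, 84834772 to 84835497) lay 10 bp from the TSS with 18 tags, a score of 216 and a fold of 21.8, and overlapped an ATAC peak assigned to the neighbouring gene Atp5j. Runx1, a regulator of blood stem cells, had 2 STAT3 peaks. The promoter peak (chromosome 16, 92825900 to 92826177) lay 36 bp downstream of the TSS with 40 tags, a score of 143 and a fold of 24.5. The other (92800829 to 92801165, intron 2 of 6) lay 25077 bp downstream with 35 tags and a fold of 37.1, and both overlapped ATAC peaks. The ATAC list assigned 58 intervals to Runx1, 11 to Stat3, 11 to Tcf7 and 3 to Sox4. No peak of the 3 factors was assigned to Stat3, Sox4 or Tcf7, a Wnt pathway factor of blood precursors, in lists that may lack their strongest peaks (implied ranks of the strongest listed peak 102, 102 and 21 for STAT3, SOX4 and GABPa).

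**Figure D5:**
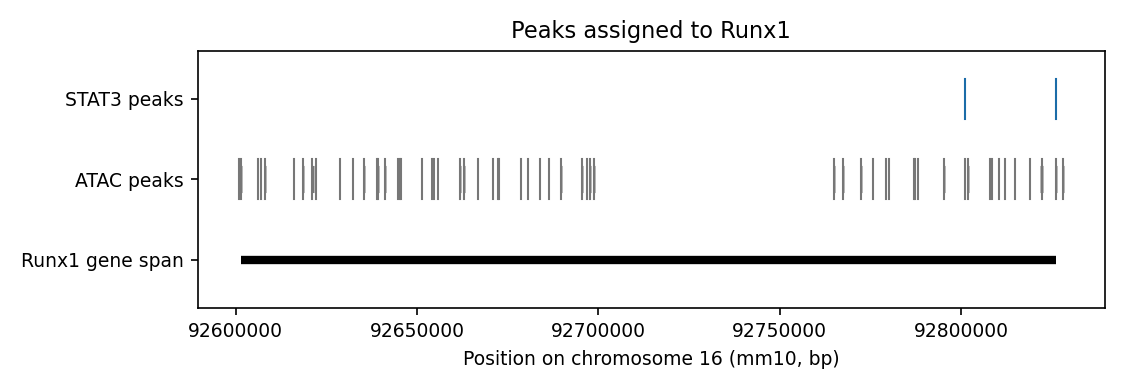
Horizontal position is the mm10 coordinate on chromosome 16, with the Runx1 gene span (92601466 to 92826074) as a black line and vertical marks at each ATAC and STAT3 peak that the lists assign to Runx1. The 2 STAT3 peaks lie in the part of the gene near its TSS and 58 ATAC intervals are assigned to it, with none between 92699038 and 92764879.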

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

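All tests in this part were chosen only after the results were seen, as were the values singled out.

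The repeat annotation and the chromosome column, which no comparison above set out to use, held signals above the limit of 3 peaks that would be compatible with none. GABPa had 287 peaks in young LINE-1 elements (names starting L1Md) and 183 on the Y chromosome, where 58 peaks were assigned to the multi-copy gene Gm20736. Of its LINE-1 peaks 46.1% (42.2 to 50.1) carried such a name, against 3.43% (1.39 to 6.94) for SOX4 and 3.64% for ATAC. Reads shared between near-identical copies could give such an excess, and so could binding to young elements. The share was computed from the flagged peaks themselves, so it cannot tell these apart. Binding to elements open in these cells would need open LINE-1 peaks, and 2.41% (1.36 to 3.95) overlapped an ATAC peak against 15.0% of placements in gene bodies. That value leaves binding open, since ATAC was measured in the other population and short reads may not be placed in young copies, and the sorted population itself was not tested as a biological explanation.

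The false discovery rate column, also outside the planned comparisons, was high in the strongest peaks of each list, and for STAT3 and SOX4 also in the weakest, with medians of 4.35% and 3.39% in the 10 lowest scores. The strongest listed peak had a rate of 4.90% for STAT3 and SOX4 and 4.76% for GABPa, although a top-ranked peak would have 0 or a far larger rate. Read as exchanged-sample peaks over called peaks, these rates imply ranks of 102, 102 and 21, so that 101, 101 and 20 stronger peaks may be absent from the lists. For STAT3 and GABPa all 10 strongest peaks fell on 1 such series of increasing ranks, reaching 112 and 31, and for SOX4 5 did. The authors' limit under 5% is thus a candidate cause of the missing top peaks, and the named strongest genes are those of the filtered lists. No biological explanation was tested.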

How the results depend on the processing

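Repeats left out and placements in gene bodies, or only at genes with at least 2 listed peaks, were added after seeing the data. For ratios, promoter shares, shared peaks and genes, and numbers of lists, the alternatives left 63 values inside the 95% interval of the main value or within 1.5 times its count, moved 54 and turned 4. For open shares and score differences they left 22, moved 17 and turned none. Part of the values left could not have changed. Another placement leaves an observed open share or shared-peak count as it is, and the factor lists had no repeated entries to merge. These tallies therefore do not measure how stable the results are. STAT3 peaks stayed above their placements throughout. The causes were not tested. No paired analysis was possible because each group had 1 library and no replicate numbers. Motif alternatives were not run without a genome sequence, nor the stronger ATAC peaks without a score. Tags per peak were the only depth known, and the effect of depth on the shares was not tested.

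The main ratios to placements (STAT3 25.1, SOX4 2.39, GABPa 2.84) used the whole genome and are raised by the limit of the lists to genes. Distance-matched placement gave 3.88, 0.990 and 0.904, turning SOX4 and GABPa below 1. Limited to genes with at least 2 listed peaks, a version used first and replaced after its values were seen, it gave 2.78, 0.805 and 0.709, again turning both. Gene-body placement gave 12.6, 1.18 and 1.21, and 11.2, 1.05 and 1.08 in that first version. A 50% overlap gave 78.3, 2.03 and 12.7, peak centres 58.3 (STAT3) and 6.22 (GABPa), fixed 200 bp widths 31.8 and 4.83, scores above the median 27.7 and 4.62, and repeats left out 26.5, 2.96 and 4.73. With repeats left out of the factor lists, the placements could still fall in repeats.

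Promoter shares in percent (STAT3 47.0, SOX4 5.31, GABPa 14.0, ATAC 25.9) became 65.4, 28.7, 33.1 and 40.3 with a 5000 bp window, 43.1, 3.45, 10.9 and 15.8 by the authors' label, and 54.6, 7.73, 26.8 and 31.0 without repeats. Scores above the median gave 53.3 for STAT3 and 22.9 for GABPa, and ATAC gave 14.1 with entries merged and 25.5 on autosomes.

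Shared peaks of SOX4 with GABPa (51) fell to 14 with fixed widths, 18 above the median score and 28 without repeats. Means of random placements fell from 3.54 to 1.13, 0.735 and 1.15. Shared peaks of SOX4 with STAT3 (58) fell to 7 above the median score (random placements 0.573 to 0.156). Those of STAT3 with GABPa (71) fell to 24 with fixed widths (1.135 to 0.302). Genes shared by SOX4 and STAT3 (11), SOX4 and GABPa (12) and STAT3 and GABPa (52) were 208, 467 and 147 by nearest gene. Independent lists would share 107, 249 and 81.8, so the ratios fell from 3.51, 4.93 and 8.23 to 1.94, 1.88 and 1.80. With 5000 bp the first pair had 51 against 23.0 and the second 47 against 30.3. Above the median score they had 2 against 0.953 and 5 against 1.08. The second had 6 against 1.80 with open promoters as background. By nearest gene the lists above the random range were 3 for STAT3, 1 for SOX4, 1 for GABPa and 0 for ATAC in place of 6, 0, 6 and 12, and 2 for ATAC with 5000 bp. The random lists were not matched on gene length.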

Other observations

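The tests of explanations in this part were chosen only after the results were seen, apart from the share of SOX4 peaks outside open chromatin, which was set down before.

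Peaks on the X chromosome were sparse in every lin-CD34+ list. The X held 0.431% (0.230 to 0.736) of SOX4 peaks, 0.791% (0.319 to 1.62) of STAT3 peaks and 0.610% of ATAC intervals, against 4.36% (3.59 to 5.23) of GABPa peaks in lin-CD34- cells and 4.38% of gene bodies with their upstream 5000 bp. The genes with the most ATAC intervals were long ones, Ntm with 172, Kif26b with 149 and Opcml with 147. By nearest TSS, the most SOX4 peaks were assigned to Wwox (6), Pcdh15 and Maf (5 each). The Maf gene spans 3642 bp, and a SOX4 peak assigned to it lay 552397 bp from its TSS, so that peak was outside Maf.

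SOX4 peaks overlapped ATAC peaks no more often than distance-matched placements did, at 0.990 times their share. Of STAT3 peaks outside promoters 62.5% (57.9 to 66.9) were open in the same list against 6.04% of placements in gene bodies. That argues against an ATAC list that misses most open regions bound by STAT3. It cannot exclude gaps at SOX4 sites, where STAT3 mostly had no peak. Peak numbers in the ATAC list ran to 400838 for 143365 distinct intervals, so called peaks may be absent from it. A list made mostly of background that passed the score limit was not excluded: peaks above the median score were open 1.39 percentage points more often than the others, with an interval of −0.221 to 3.01, yet the open share rose in each of 5 score classes and peaks above the median were at 1.30 times placements in gene bodies (percentile 99.7) against 1.06 for the others. That SOX4 occupied closed sites cannot be told apart from this, since 94.6% of its peaks lay outside open chromatin in either case and no motif search was run. The overlap of 58 SOX4 and STAT3 peaks, mostly closed, may come in part from a common control, if the only control library listed for lin-CD34+ cells served both, which was not tested.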
